A study of Mus musculus with 6 samples.

How the data were processed

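RNA was sequenced in bulk from 6 mouse samples taken at postnatal day 18, 3 from wild-type animals (WT) and 3 from animals lacking a large enhancer of Atoh7 (enhancer KO). The protocol and series design in the labels name the developing cerebellum, while the source and tissue fields of the same labels read retina. Markers of both tissues were therefore measured and their levels are given in the report. The labels call the libraries independent replicates and name no animal, litter, sex or sequencing day. P-values of comparisons between the groups therefore measure the spread between these samples.

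Per the submitters' processing notes, the authors trimmed reads with Trimmomatic and aligned them with STAR to the mm10 mouse genome. The versions, the gene annotation and the alignment settings are not given in the sources used here. The deposited values are whole-number read counts per gene, as STAR writes them, with an unstranded column and a column for each strand and no normalization by the authors. Each library lists 24411 gene symbols after 4 rows that name no gene, which hold reads that were unmapped, aligned to several places, outside annotated exons or ambiguous. Those 4 rows were kept out of library sizes and tests. STAR counts a read here only where it aligns to 1 place, so genes with near-identical copies, ribosomal RNA and small RNA genes are measured with less certainty. A column for 1 strand was to be used if it held at least 80% of the stranded reads in every library. Column 4 met this, with 1.62% to 1.88% of the stranded reads on the other strand, and was used throughout.

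Reads in genes ranged from 22812075 to 33076111 in the WT libraries and from 36849747 to 40858310 in the enhancer KO libraries. Of all reads, the share outside annotated exons was 32.4% ± 1.56 (SD, n = 3) in WT and 17.4% ± 0.735 (SD, n = 3) in enhancer KO. The ribosomal RNA gene Rn45s took 12.9% of gene reads in WT replicate 2 and 1.51% to 3.02% in the other libraries, and 20.4% of the reads of WT replicate 2 were unmapped. Counts of no pair of libraries matched within sampling noise: the median chi-square per gene of the closest pair, enhancer KO replicates 1 and 2, was 1.13, against 0.455 for sampling noise alone. All 6 libraries were kept as separate replicates.

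Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 15846. Libraries were scaled by TMM, and enhancer KO was compared with WT by edgeR's quasi-likelihood test (robust fit, two-sided, no fold-change minimum) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels (CPM) are counts relative to TMM-scaled library sizes, and log2 fold changes are enhancer KO over WT. The SE of a log2 fold change was derived from it and the quasi-likelihood F statistic. Lists of genes for cell types, neighbouring tissues and pathways were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Of these lists, 37 had at least 3 members tested, and their p-values were adjusted together. An estimated correlation and fry were run beside it. The list of mitochondrially encoded genes had no member in the count tables and was not tested. Shares of reads were compared by exact two-sided permutation tests, for which 3 libraries against 3 can give no p below 0.1.

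Gene positions, lengths and GC content came from GENCODE mouse release 21, which is on the same build. Of the 24411 symbols, 23334 matched a gene by symbol and 668 by an older symbol, and 409 had no unique match. Genes lying inside an intron of a gene with at least 10 CPM were split by whether they shared its strand. A trend of each library over intron length, spliced length and GC content was fitted with mgcv 1.9.3 and removed as an offset in an added alternative.

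The groups, tests, gene lists and most alternatives were set before the data were examined. The genes named were Atoh7, Robo3, the genes tested within 1 Mb of Atoh7, and the most abundant genes. To these were added up to 12 genes in each direction with the smallest adjusted p, a mean of at least 1 CPM and WT and enhancer KO ranges that did not overlap. Each list gave up to 4 members past the threshold with the smallest p, or its 2 most abundant members where none passed. A few other list members were named after their values were seen, and are said to be so. The alternatives were RLE scaling, library size alone, other filters on low counts, replicate number as a block, a minimum fold of 1.2, a threshold of 0.1, the unstranded column, an Xist covariate, removal of sex-linked or ribosomal genes, limma-voom, DESeq2 1.42.0 and leaving out each library. The trend removal and a fit without WT replicates 2 and 3 were added after the data were seen. That fit keeps WT replicate 1 as the only WT library, which alone had high Xist and no Ddx3y reads. Sex and genotype therefore cannot be told apart in it.

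The tests were checked on 5 sets of simulated counts for 15846 genes drawn from the libraries of this comparison. Of 100 genes changed by 1.5-fold, 72.4% were recovered on average, and of 100 changed by 2-fold, 88.4%. Of the calls, 8.11% were false on average. When the granule list was lowered by 1.4-fold in simulated counts, camera called it with an adjusted p of 4.92e-28, or 0.00977 with an estimated correlation. It called 0 other lists. Genes were drawn independently of each other here, so the simulation cannot show how correlation between genes affects the list calls.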

Results

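The data are gene-level RNA-seq read counts from mouse tissue at postnatal day 18, with 3 WT libraries and 3 libraries from animals without a large enhancer of Atoh7. Atoh7 encodes a basic helix-loop-helix transcription factor known for its part in making retinal ganglion cells. The series concerns a regulatory module in that process, and this comparison asks what the loss of the enhancer did to transcripts in the tissue sampled here. Total reads ranged from 57466712 to 65530873 per library, and reads in genes from 22812075 to 40858310.

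Markers of cerebellar cell types were abundant in all 6 libraries, and most photoreceptor genes had few reads. Averaged over the libraries, the granule neuron list had a mean of 195 CPM and the Purkinje list 422 CPM, against 0.531 CPM for the photoreceptor list, of which Rom1 was the most abundant at 8.54 CPM. Other retinal lists had more reads, the retinal ganglion list with 142 CPM in WT and 150 CPM in enhancer KO and the inner retina list with 21.8 and 26.6 CPM. The most abundant gene of the inner retina list, Pcp2, is also on the Purkinje list, and that of the ganglion list, the neurofilament gene Nefl, named after its values were seen, is expressed in many neurons. Hox genes of the hindbrain were also read in every library, with Hoxb3, named after its values were seen, at 11.5 CPM in WT and 12.2 CPM in enhancer KO. The labels give both cerebellum and retina for these samples. Across the libraries the photoreceptor list ranged from 0.440 to 0.731 CPM. The granule list ranged from 136 to 259 CPM and the Purkinje list from 336 to 480 CPM. These levels argue against retina as the main tissue of any library. No test was made of them.

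Atoh7 transcripts were fewer in the enhancer KO libraries. The gene lies on chromosome 10 at 63099651 to 63101279 of mm10, on the plus strand. Its level was 2.04 ± 0.0945 CPM (SD, n = 3) in WT and 0.766 ± 0.0835 CPM (SD, n = 3) in enhancer KO, from 63, 42 and 72 reads in the WT libraries and 28, 33 and 29 in the enhancer KO libraries. The log2 fold change was -1.41 ± 0.206 (SE; edgeR adjusted p = 0.000353), a fall of 62.4%, and every enhancer KO library lay below every WT library. Atoh7 was weakly expressed in both groups. Robo3, an axon guidance receptor gene, had 0.967 ± 0.587 CPM in WT and 0.612 ± 0.123 CPM in enhancer KO (SD, n = 3) and did not pass (log2 fold change -0.68 ± 0.400, SE; edgeR adjusted p = 0.225). Without WT replicate 1, the library with the most Robo3 reads, its log2 fold change was -0.0090. Without both WT replicates 2 and 3, a fit in which the lone WT library is assumed to vary like the enhancer KO libraries, Robo3 was called lower (edgeR adjusted p = 0.0195).

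**Figure D1:**
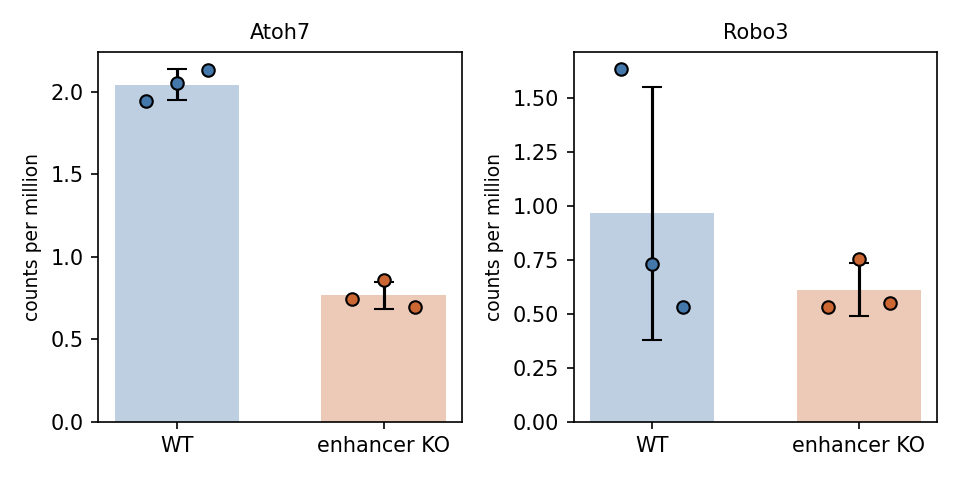
Level of Atoh7 and Robo3 in CPM (vertical axes) in WT and enhancer KO libraries. Bars are means, error bars are SD and points are the 3 libraries of each group. Atoh7 averaged 2.04 CPM in WT and 0.766 CPM in enhancer KO with no overlap, and the Robo3 libraries overlapped.

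Several neighbours of Atoh7 also had fewer transcripts. Where the deletion lies is not given in the labels, so a lower count may reflect deleted sequence or altered expression. Of the 32 neighbours counted within 1 Mb, 28 were tested, and 9 fell and 1 rose, both over all genes and adjusted over the list alone. Dna2, a DNA replication helicase and nuclease, fell from 3.07 ± 0.127 to 1.33 ± 0.266 CPM (SD, n = 3; edgeR adjusted p = 0.000620). Rufy2 had a log2 fold change of -0.67 ± 0.0510 and the RNA-binding gene Hnrnph3 of -0.56 ± 0.0741 (SE). Sirt1, a deacetylase gene, fell by 0.42 on the log2 scale and Ccar1 by 0.31. Herc4 and Lrrtm3 fell by 0.24 and 0.23, and the small RNA genes Snord98 and Mir7662 by 1.79 and 1.29. Snord98 lies in an intron of Ccar1 and Mir7662 within the span of Tspan15, each on the strand of that gene. Genes in same-strand introns had a median log2 fold change of -1.27 across the genome, and reads outside exons were fewer in enhancer KO (17.4% against 32.4%). With the trend over gene structure removed, Snord98 was at -0.75 and Mir7662 at -0.21, and neither passed (edgeR adjusted p = 0.212 and 0.741). Slc25a16, a mitochondrial carrier gene, rose with a log2 fold change of 0.21 ± 0.0648 (SE; edgeR adjusted p = 0.0263). Mypn, the gene nearest to Atoh7 among those tested, had a log2 fold change of 0.48 ± 0.255 (SE) and did not pass (edgeR adjusted p = 0.177), and was at 0.16 without enhancer KO replicate 2. Hk1, Tet1, Tspan15, Vps26a, Kif1bp, Supv3l1, Ddx50, Dnajc12, Ctnna3, Pbld2 and Hk1os also did not pass, except Tspan15 without WT replicate 2 (edgeR adjusted p = 0.0422). Of the neighbours tested 35.7% were called, against 31.3% of all genes tested. By direction, 9 of 28 neighbours were lower and 1 higher, against 2844 lower and 2120 higher of all 15846 genes tested. These differences were not tested. The fixed list of this region, which includes Atoh7 itself, did not pass camera (adjusted p = 0.0565). It passed without enhancer KO replicate 3 (adjusted p = 0.0342). Slc25a16 lost its call without WT replicate 1 or 2 or enhancer KO replicate 2 or 3 (edgeR adjusted p = 0.0622, 0.0728, 0.0512 and 0.0862). Mir7662 lost it without WT replicate 2 or 3 or enhancer KO replicate 1 or 3 (0.0777, 0.0687, 0.0916 and 0.0741), and Lrrtm3 without WT replicate 2 or enhancer KO replicate 1 or 2 (0.0572, 0.0587 and 0.0505). With library size alone Lrrtm3 lost it (0.122), as did Herc4 at a log2 fold change of -0.18.

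Across all genes, several long noncoding RNAs were among the clearest falls. The lower genes with the smallest adjusted p included the long noncoding RNAs Kcnq1ot1 (3.35-fold lower in enhancer KO), Ftx (3.69-fold), Ipw (3.30-fold) and Firre (2.19-fold). They also included Pnisr (2.58-fold), Snrnp70 (2.32-fold), Ccnl2 (2.42-fold), Leng8 (2.75-fold), Nktr (1.98-fold), 9530091C08Rik (4.61-fold), Ddx26b (2.39-fold) and Wsb1 (2.26-fold). The higher genes with the smallest adjusted p changed less. The membrane protein gene Tmem47 rose from 128 ± 2.51 to 186 ± 4.69 CPM and the potassium channel gene Kcnj16 from 51.0 ± 1.67 to 73.7 ± 2.21 CPM (SD, n = 3). Log2 fold changes were 0.58 for 1500009C09Rik, 0.51 for the small ubiquitin-like modifier gene Sumo3, 0.48 for the dynein light chain gene Dynll2 and 0.42 for Mtpn. They were 0.45 for Rnd2, 0.44 for the ribosomal protein gene Rpl9, 0.43 for the centromere protein gene Cenpb, 0.39 for 2900097C17Rik, 0.38 for Selt and 0.36 for Csrp1. These 24 genes had edgeR adjusted p from 2.78e-08 to 3.97e-05. Among the most abundant genes, Mbp rose by 0.16 on the log2 scale, while Rn45s did not pass (edgeR adjusted p = 0.137). Mbp lost its call without WT replicate 1 or 3 or enhancer KO replicate 2 (0.0850, 0.0998 and 0.0803). Rn45s was called lower without WT replicate 2 (2.10e-06).

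Of 15846 genes tested, 4964 changed at an edgeR adjusted p under 0.05, 2120 of them higher and 2844 lower in enhancer KO. More than 2-fold changes were found for 20 higher and 344 lower genes, and the median change was 17.1% among the higher and 23.2% among the lower. Ranges of the groups did not overlap for 44.8% of the genes tested, against 10% by chance. Lower genes made up 57.3% of the calls, 43.8% with library size alone, when 1689 were lower, and 44.0% with the trend over gene structure removed. With a minimum fold of 1.2, 83 genes were higher and 908 lower. Most list calls were lost with it, leaving 4 higher ribosomal protein genes of 52, 1 Purkinje gene of 12, 0 astroglial genes of 6 and 0 microglial genes of 5, beside 6 higher interferon genes of 9 and 7 lower granule neuron genes of 16. Without WT replicates 2 and 3, a fit added after the data were seen, 1489 were higher and 1640 lower.

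Nuclear long noncoding RNAs formed the list with the lowest median. Of its 10 members, 9 fell and 0 rose, over all genes and adjusted over the list alone, with a median log2 fold change of -1.27 (camera adjusted p = 3.85e-05). It did not pass with an estimated correlation (adjusted p = 0.662). Malat1 fell from 13053 ± 333 to 5272 ± 683 CPM, Snhg11 from 617 ± 128 to 213 ± 9.99 CPM and Mirg from 13.8 ± 1.32 to 4.55 ± 0.421 CPM (SD, n = 3). The share of all reads outside annotated exons moved with this list, being 15.0 percentage points lower in enhancer KO than in WT. That share was 31.1% to 34.1% in the WT libraries and 16.8% to 18.2% in the enhancer KO libraries (exact permutation p = 0.1, the smallest that 3 against 3 allows). The list of small and ribosomal RNA, with Rn45s and the RNase P RNA gene Rpph1 as its most abundant members, had 0 members called of 5 by edgeR. Without WT replicate 2, Rn45s was called lower (log2 fold change -0.90 against -2.10 with all libraries, edgeR adjusted p = 2.10e-06), and without WT replicate 1 or 2 Rpph1 was called higher (0.00693 and 0.0203), as it was with library size alone (0.000491).

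**Figure D2:**
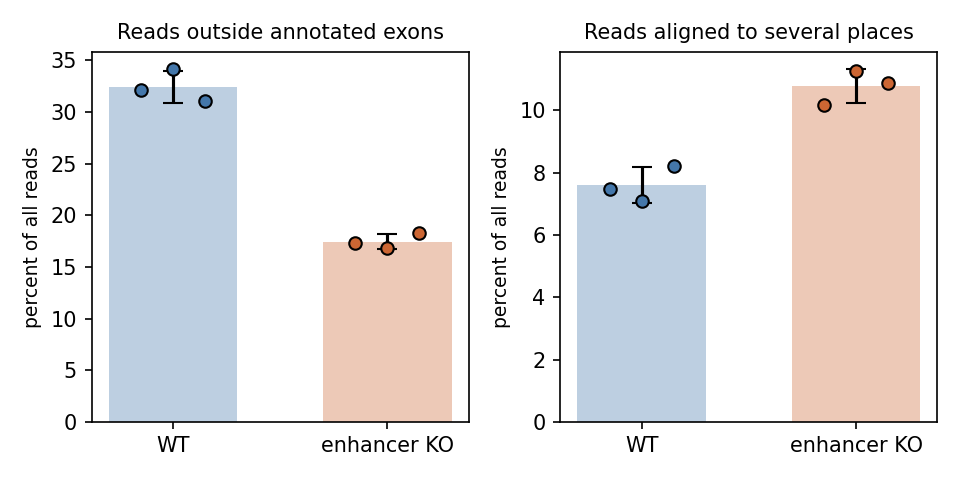
Share of all reads outside annotated exons and share aligned to several places, in percent (vertical axes), for WT and enhancer KO. Bars are means, error bars are SD and points are the 3 libraries of each group. Reads outside exons averaged 32.4% in WT and 17.4% in enhancer KO, and reads aligned to several places 7.60% and 10.8%.

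Markers of cerebellar granule neurons, the small excitatory neurons of the granule layer, were lower as a group. All 16 members fell, over all genes and adjusted over the list alone, with a median log2 fold change of -0.64 (camera adjusted p = 3.50e-07; 0.662 with an estimated correlation). The extracellular matrix gene Reln fell from 322 ± 17.8 to 189 ± 8.87 CPM, the transcription factor gene Zic2 from 182 ± 19.6 to 124 ± 4.25 CPM, Tiam1 from 159 ± 1.89 to 117 ± 9.29 CPM and the potassium channel gene Kcnd2 from 148 ± 8.91 to 107 ± 8.18 CPM (SD, n = 3). The reads outside exons were fewer in the same libraries, 17.4% against 32.4%. Without WT replicate 2, 10 members were lower, without enhancer KO replicate 1, 9, and without enhancer KO replicate 2, 10. Without both WT replicates 2 and 3, which had the fewest reads on several midbrain genes, the median was -0.41. The WT library then left also differed from the enhancer KO libraries in Xist and Ddx3y.

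Granule cell precursor and proneural genes did not pass as lists. Of 13 precursor genes tested, 3 fell and 0 rose, over all genes and over the list alone, and the list did not pass (camera adjusted p = 0.257; 0.662 with an estimated correlation). The hedgehog co-receptor gene Boc had a log2 fold change of -0.65 ± 0.0637, Cntn2 of -0.45 ± 0.0470 and Nhlh2 of -0.48 ± 0.0984 (SE). Without WT replicate 1, 5 precursor genes were lower, and without enhancer KO replicate 3, 3 were higher. Of 12 proneural basic helix-loop-helix genes tested, 4 fell over all genes, and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.302). Besides Nhlh2, Neurod1, Neurod2 and Atoh8 fell by 0.62, 0.40 and 0.37 on the log2 scale. Neurod1 lost its call without WT replicate 1, 2 or 3 or enhancer KO replicate 1 or 2 (edgeR adjusted p from 0.0641 to 0.104), and Neurod2 without WT replicate 2 or enhancer KO replicate 1 or 2 (0.0880, 0.0987 and 0.0900). Atoh8 lost it without WT replicate 2 or 3 or enhancer KO replicate 1, 2 or 3 (0.102, 0.142, 0.0740, 0.0549 and 0.126) and with library size alone (0.142). Proliferation genes had 0 of 20 members called by edgeR, with Pcna at 34.4 CPM in WT and 35.8 CPM in enhancer KO and Mcm4 at 12.9 and 12.8 CPM. Without WT replicate 3, 1 proliferation gene was higher, and without enhancer KO replicate 2, 1 was lower. Immature neuron genes had 2 of 14 members higher, Gap43 and Nnat, and Nnat lost its call without WT replicate 1 or enhancer KO replicate 2 (edgeR adjusted p = 0.0962 and 0.0503).

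Purkinje cell markers were higher as a group. Of 22 members, 12 rose and 0 fell over all genes, and 13 rose adjusted over the list alone, with a median log2 fold change of 0.29 (camera adjusted p = 5.16e-05), and did not pass with an estimated correlation (adjusted p = 0.662). Rgs8 rose from 624 ± 49.0 to 852 ± 55.2 CPM, the glycolytic gene Aldoc from 1459 ± 77.8 to 1791 ± 43.9 CPM, the nuclear receptor gene Rora from 503 ± 31.9 to 629 ± 11.9 CPM and the calcium channel gene Itpr1 from 1919 ± 151 to 2373 ± 106 CPM (SD, n = 3). Without enhancer KO replicate 1, 7 members were higher. The libraries with more Purkinje transcripts had the fewer reads outside exons, 17.4% against 32.4%. Of 18 interneuron genes, 5 rose and 2 fell over all genes, and 8 rose and 3 fell adjusted over the list alone. Lypd6 rose by 0.45, Gad1, which makes GABA, by 0.25 and its vesicular transporter Slc32a1 by 0.23 on the log2 scale, and Ptprk fell by 0.29. The interneuron list did not pass (camera adjusted p = 0.171).

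**Figure D3:**
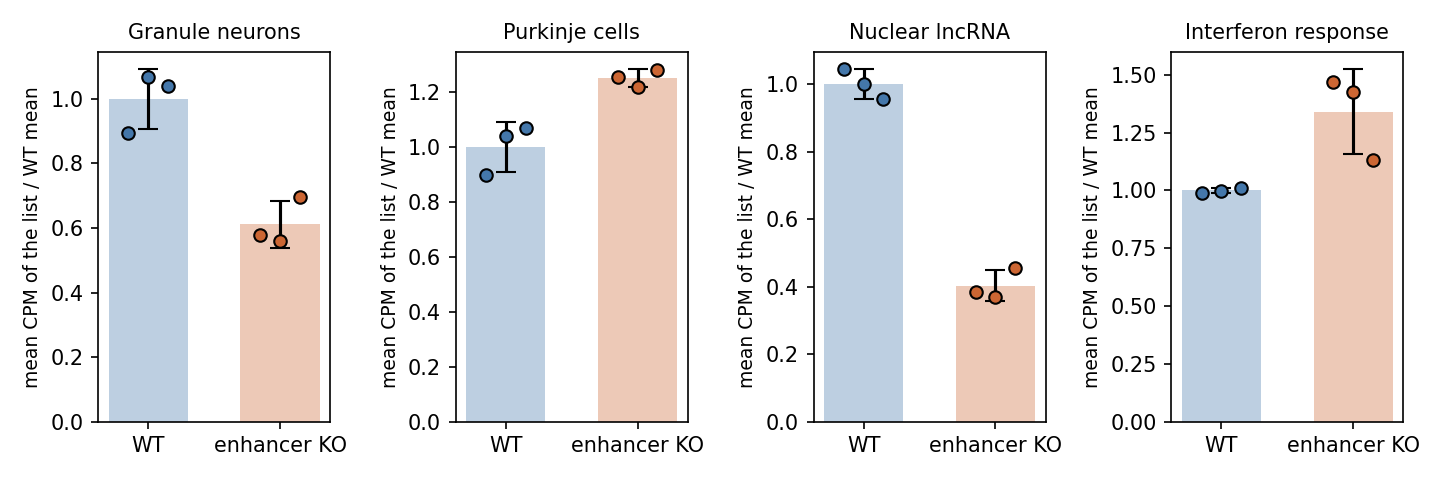
Mean CPM of the genes in 4 lists in each library, divided by the WT mean (vertical axes). Bars are group means, error bars are SD and points are the 3 libraries of each group. Granule neuron and nuclear RNA lists lay lower in every enhancer KO library than in any WT library, and Purkinje and interferon lists lay higher.

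Receptor genes moved in both directions, in libraries that also differed in reads outside exons (17.4% in enhancer KO, 32.4% in WT). Across all 15846 genes tested, 2120 rose and 2844 fell. GABA and glycine receptor genes had 5 members higher and 3 lower of 20 over all genes, and 7 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0333, higher; 0.662 with an estimated correlation). Gabbr1 rose by 0.29, Gabbr2 by 0.21, Gabra4 by 0.33 and Gabra3 by 0.42 on the log2 scale. The lower members, named after their values were seen, were Gabra6, from 320 ± 69.4 to 159 ± 34.9 CPM, Gabrd, from 39.6 ± 6.84 to 23.9 ± 3.01 CPM, and Gphn, from 93.2 ± 5.87 to 81.7 ± 3.47 CPM (SD, n = 3), of which Gabra6 and Gabrd are also on the granule neuron list. Gabra6 lost its call without WT replicate 1, 2 or 3 or enhancer KO replicate 1 or 2 (edgeR adjusted p from 0.0583 to 0.129) and Gabrd without enhancer KO replicate 1 (0.0634). Gphn lost it without WT replicate 2 or enhancer KO replicate 1 or 2 (0.0990, 0.0714 and 0.0762) and with library size alone (0.234). The list's call was lost without WT replicate 3 or enhancer KO replicate 3 (camera adjusted p = 0.124 and 0.0623), with library size alone (0.0653) and with the trend over gene structure removed (0.0554). Its lower members were 1 without WT replicate 2, 0 without enhancer KO replicate 1 and 1 without enhancer KO replicate 2. Glutamate receptor genes had 6 higher and 7 lower of 24, over all genes and over the list alone, and did not pass (camera adjusted p = 0.950). Gria1 rose by 0.36 on the log2 scale, while Gria2, Grik2 and Grm4 fell by 0.49, 0.83 and 0.63. Without enhancer KO replicate 1, 3 of the glutamate receptor genes were higher.

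Astroglial and microglial markers were higher and endothelial markers lower. Of 16 Bergmann glia and astrocyte genes, 6 rose over all genes and 10 over the list alone (camera adjusted p = 0.00155, median log2 fold change 0.21), among them the glutamate transporter gene Slc1a2 from 3181 ± 173 to 3980 ± 112 CPM (SD, n = 3) and the connexin genes Gja1 and Gjb6. Of 15 microglial genes, 5 rose over all genes and over the list alone (camera adjusted p = 0.00149), with log2 fold changes of 0.43 for Cx3cr1 and 0.34 for Ctss. Of 13 endothelial genes, 9 fell over all genes and over the list alone (camera adjusted p = 0.000772, median -0.33), with Ly6c1 at -0.68, Esam at -0.58, Slco1a4 at -0.50 and Pecam1 at -0.40. With an estimated correlation the adjusted p was 0.662 for each of these lists, and these libraries differed in reads outside exons too (17.4% against 32.4%). The count of higher astroglial genes was 3 without enhancer KO replicate 2 and 10 with library size alone, and that of microglial genes was 3 without WT replicate 3 or enhancer KO replicate 2 and 11 without enhancer KO replicate 3. Without both WT replicates 2 and 3, 4 endothelial and 2 microglial genes were called.

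Oligodendrocyte, vascular wall, choroid plexus and meningeal lists did not pass, while ependymal markers were higher. The share of reads outside exons differed between the groups too (17.4% in enhancer KO, 32.4% in WT). Of 18 myelin genes, 1 rose and 2 fell (Mbp higher, Mag and Myrf lower; camera adjusted p = 0.951), and Mbp lost its call without WT replicate 1 or 3 or enhancer KO replicate 2 (edgeR adjusted p = 0.0850, 0.0998 and 0.0803). Mag and Myrf lost theirs with library size alone (0.0558 and 0.241), when 2 myelin genes were higher. Higher myelin genes were 4 without WT replicate 2 and 3 without enhancer KO replicate 1, and 3 were lower without enhancer KO replicate 2. Of 12 oligodendrocyte precursor genes, 1 rose and 3 fell over all genes, and 3 rose and 4 fell over the list alone. Vcan, Sox10 and Cspg4 fell by 0.48, 0.28 and 0.38 on the log2 scale, and Lhfpl3, the higher member, lost its call without each library except WT replicate 1 (0.0559 to 0.143) and with library size alone (0.0597). Abcc9 alone of 10 mural genes was called, with a log2 fold change of -0.40, and without enhancer KO replicate 1, 2 were. Choroid plexus genes had 0 of 17 members called and meningeal genes 0 of 14 by edgeR, with Ttr at 1387 ± 320 CPM in WT and 1438 ± 614 CPM in enhancer KO (SD, n = 3), of which enhancer KO replicate 3 had 736 CPM. Without that library the choroid plexus list was called higher (camera adjusted p = 0.00658, 4 members higher), as was the meningeal list (0.000486, 6 higher). Enpp2, Igf2 and Ptgds, the other abundant members, did not pass with all libraries, and Igf2 did without enhancer KO replicate 3 (edgeR adjusted p = 0.0450). Of 11 ependymal genes, 3 rose over all genes and 5 over the list alone (median log2 fold change 0.54, camera adjusted p = 0.00846; 0.662 with an estimated correlation), with Foxj1, a regulator of motile cilia, at 25.4 CPM in WT and 32.3 CPM in enhancer KO. Rsph1 and 1700012B09Rik, the other ependymal members called, lost the call without WT replicate 3 or enhancer KO replicate 1 or 2, Rsph1 also without WT replicate 1 and 1700012B09Rik without WT replicate 2 (edgeR adjusted p from 0.0739 to 0.159). Ependymal genes higher were 2 without WT replicate 1, 2 or 3, 1 without enhancer KO replicate 1 or 2, 8 without enhancer KO replicate 3 and 6 with library size alone. In the blood list, where 3 genes were tested, Bpgm rose by 0.21, and without WT replicate 2, 2 genes and the list were called (camera adjusted p = 0.0302).

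Genes of translation and respiration were slightly higher. Of 80 ribosomal protein genes, 52 rose and 0 fell over all genes, and 60 rose over the list alone, with a median log2 fold change of 0.21 (camera adjusted p = 2.56e-12). Rps2, Rpl9 and Rpl14 rose by 0.43, 0.44 and 0.38. Of 24 nuclear respiratory chain genes, 7 rose over all genes and over the list alone (camera adjusted p = 0.00272, median 0.11), including Ndufb9 at 0.37, Ndufa2 at 0.32, Cox4i1 at 0.26 and Cox5a at 0.24. With an estimated correlation the adjusted p was 0.662 for both lists. The call of the respiratory list was lost without WT replicate 1 (camera adjusted p = 0.0546) and with the trend over gene structure removed (0.144). Its median was 0.055 without WT replicate 1 and 0.18 without WT replicate 2, and with library size alone 11 members were higher with a median of 0.18. The libraries with higher ribosomal protein levels also had fewer reads outside exons. Of 16 sterol synthesis genes, 4 fell over all genes and 3 over the list alone (Lss and Mvd among them; camera adjusted p = 0.675), and with library size alone 0 did (edgeR adjusted p = 0.338 for Lss and 0.421 for Mvd). The sterol count was 0 without WT replicate 2, 1 without enhancer KO replicate 1 and 2 without enhancer KO replicate 3.

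Lists of heat shock, glucocorticoid and interferon response transcripts were higher with the preset correlation. With a minimum fold of 1.2, 0 heat shock and 2 glucocorticoid genes stayed higher. Of 14 interferon response genes, 9 rose over all genes and over the list alone, with a median log2 fold change of 0.70 (camera adjusted p = 0.000176). Oasl2 rose from 3.47 ± 0.232 to 7.04 ± 1.57 CPM and Ifit3 from 4.81 ± 0.325 to 9.54 ± 2.40 CPM (SD, n = 3), with Ifit3b and Irf7 at log2 fold changes of 0.92 and 0.86. Reads outside exons were 17.4% in the same enhancer KO libraries, against 32.4% in WT. Without WT replicates 2 and 3, 2 of these genes were called. Of 10 heat shock genes, 5 rose over all genes and 6 over the list alone (camera adjusted p = 0.00846), with the chaperone genes Dnajb1 at 0.37, Hspe1 at 0.28, Hspd1 at 0.15 and Hspa1b at 0.75 on the log2 scale. Of 11 glucocorticoid response genes, 5 rose over all genes and over the list alone (camera adjusted p = 0.0146), with Mt1 at 0.53, Zbtb16 at 0.60, Fkbp5 at 0.43 and Tsc22d3 at 0.20. With an estimated correlation the adjusted p was 0.662 for these 3 lists. Hspa1b lost its call without WT replicate 2 or 3 or enhancer KO replicate 1 or 2 (edgeR adjusted p = 0.0739, 0.0979, 0.0623 and 0.0746) and Hspd1 without enhancer KO replicate 2 (0.0615). Heat shock counts were 3 without WT replicate 2 or 3 or enhancer KO replicate 1 and 2 without enhancer KO replicate 2, and the glucocorticoid list lost its call without WT replicate 1 (camera adjusted p = 0.0638). Immediate early genes had 4 of 18 higher over all genes and 3 over the list alone, Nr4a3, Fosl2, Fos and Egr3, and the list did not pass (camera adjusted p = 0.140) except without WT replicate 1 or 3 (0.0478 and 0.0434). Fos lost its call without WT replicate 1 or 2 or enhancer KO replicate 3 (edgeR adjusted p = 0.103, 0.0797 and 0.0673), and Egr3 without any library but WT replicate 1 (0.0712 to 0.120) and with library size alone (0.0985). The immediate early count was 2 without WT replicate 2 or enhancer KO replicate 3. Of 15 clock genes, Hlf rose and Per3, Per2 and Arntl fell. Arntl lost its call without WT replicate 2 or 3 or enhancer KO replicate 1 or 2 (0.0774, 0.0624, 0.0957 and 0.0511) and with library size alone (0.135), and without WT replicate 1 or enhancer KO replicate 2, 2 clock genes were higher.

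Axon guidance genes moved both ways, as did all genes tested, of which 2120 of 15846 rose and 2844 fell. Of 53 members, 7 rose and 12 fell, over all genes and over the list alone, and the list did not pass (camera adjusted p = 0.557). With the trend over gene structure removed, 13 rose and 10 fell, and the median log2 fold change was 0.060 against -0.045 before. Plxna3 had a log2 fold change of -0.63 ± 0.0832, the netrin receptor gene Unc5b of -0.34 ± 0.0383 and Plxna2 of -0.32 ± 0.0410 (SE). Without WT replicate 1, 12 members were higher, and without enhancer KO replicate 1 or 2, 4. Of 13 genes of the retinal ganglion list tested, Thy1 rose by 0.23 and the rest did not pass (camera adjusted p = 0.157; 0.0383 without WT replicate 2). Without WT replicate 1 or enhancer KO replicate 3, 3 of them were higher. In the inner retina list 0 of 7 were called by edgeR, with Pcp2 and Tfap2a, which are also on cerebellar lists, as its most abundant members. Of 5 photoreceptor genes tested, Rom1 rose by 0.61 and Rcvrn fell by 1.62, and Rom1 was at 0.40 without enhancer KO replicate 2 and lost its call without WT replicate 1 (edgeR adjusted p = 0.0615). Of 21 brainstem and midbrain genes, Th and Dbh, which make catecholamines, rose by 0.49 and 0.40 and Barhl2 fell by 0.37 (camera adjusted p = 0.0914). This list passed without WT replicate 1, WT replicate 2 or enhancer KO replicate 3 (camera adjusted p = 0.0372, 0.0270 and 0.0410), with 5 members higher without WT replicate 1 or enhancer KO replicate 3. Barhl2 lost its call without WT replicate 3 or enhancer KO replicate 1 or 2 (edgeR adjusted p = 0.0612, 0.0656 and 0.0527). Of 9 forebrain genes tested, Ppp1r1b rose by 0.27, and lost its call without enhancer KO replicate 1, 2 or 3 (0.0550, 0.0541 and 0.0593). It was at 0.18 without WT replicate 1, when 4 forebrain genes were higher, against 2 without WT replicate 2 or with library size alone. Xist was at 1054 CPM in WT replicate 1 and between 0.743 and 1.37 CPM in the other libraries, and the Y-linked gene Ddx3y had 0 reads in WT replicate 1 and 91.4 to 106 CPM elsewhere. Neither passed (edgeR adjusted p = 0.172 and 0.715), and without WT replicate 1 Ddx3y was called higher (0.0262) and 3 other members of the sex-linked list lower.

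**Figure D4:**
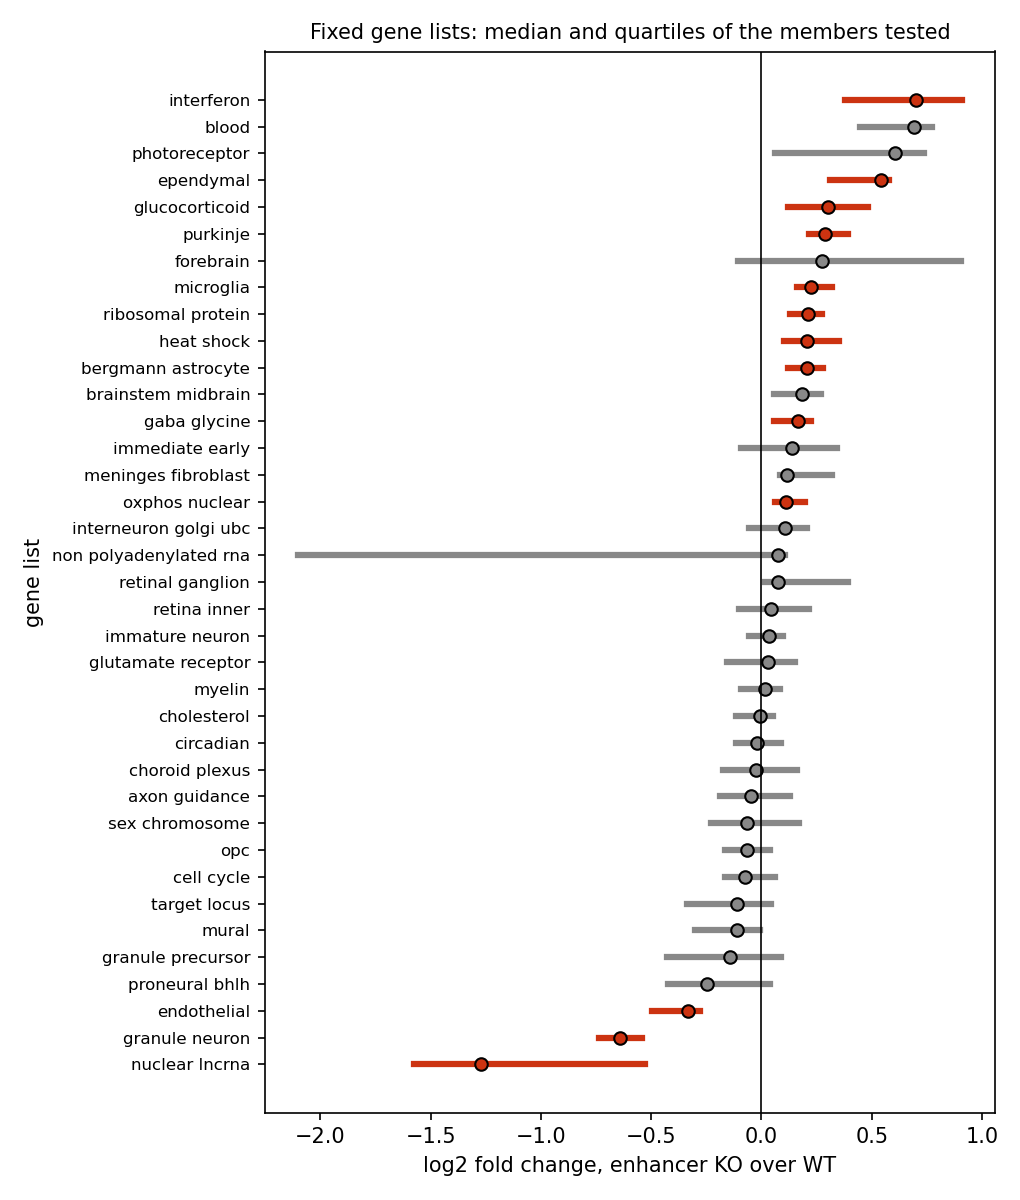
Log2 fold change of enhancer KO over WT (horizontal axis) for each fixed gene list (vertical axis). Points are medians and lines join the quartiles of the members tested, in red where camera with a preset correlation passed. The 3 red lists with medians below 0 are nuclear RNA, granule neuron and endothelial, and 10 lists above 0 are red, while 0 lists passed with an estimated correlation.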

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

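The tests of genomic DNA and of a batch were chosen only after the result was seen; the tests of unspliced RNA, of ribosomal RNA and of other splits of the libraries were set before it. In the reads that aligned to several places, which no gene count uses, the share was 10.8% ± 0.550 (SD, n = 3) in enhancer KO, above the 7.60% ± 0.563 (SD, n = 3) of WT (exact permutation p = 0.1, the smallest that 3 against 3 allows).

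Nuclear-retained transcripts and reads outside exons were both lower in enhancer KO, and unspliced RNA making up a larger part of the WT libraries is a candidate explanation. Among genes inside an intron of an expressed gene, the 95 on the strand of that gene had a median log2 fold change of -1.27. The 80 on the opposite strand had 0.06, a difference of -1.33. Permuting the strand labels over these genes gave p = 1e-05, the smallest these permutations can give. That p takes genes as its units and does not measure the spread between libraries. Genomic DNA in the WT libraries is argued against by reads on olfactory receptor genes, whose ratio of WT to enhancer KO was 0.898. Without ribosomal and abundant small RNA genes, 2656 genes were lower, against 2844 with them. Both fits were TMM-scaled, which already largely offsets reads taken by a few genes. The count therefore cannot decide whether ribosomal RNA or a few other genes took reads. With library size alone, 1689 were lower. A library or sequencing batch that follows the genotype cannot be told apart from the genotype, since the labels give no batch, the set name in the titles is the same for all 6 libraries, and the share of reads outside exons differed by -15.0 percentage points with no overlap. An effect of the enhancer loss on RNA processing stays open and was not tested.

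The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split gave 4964 changed genes, the highest of the other splits gave 0, and 1 split, the real one, gave as many.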

How the results depend on the processing

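The trend removal and the fit without WT replicates 2 and 3 were chosen after the data were seen, and in the latter the lone WT library is assumed to vary like the enhancer KO libraries; the cause of the differences below was not tested unless stated. The Atoh7 log2 fold change stayed between -1.50 and -1.32 and past the threshold in every alternative that tested it; the filter of 50 reads removed it. Over all alternatives, 2772 results for named genes kept direction and side of the threshold, 266 lost the call, 31 gained it and 51 changed sign, all of the last in genes that were not called. Atoh7 had 28 to 72 reads per library. Replicate number as a block gave 4596 genes, 1961 higher and 2635 lower. Correlations of the deviations of same-numbered libraries were 0.053, -0.039 and -0.080, and WT replicate 2 correlated best with enhancer KO replicate 3 (0.118). Such small correlations give no sign of pairing by number. They cannot exclude a litter or day shared by same-numbered libraries.

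With a minimum fold of 1.2, which by construction calls fewer genes, 991 genes changed, 83 higher and 908 lower, and 5 genes within 1 Mb, Atoh7 included, all 5 lower. Without WT replicates 2 and 3, 3129 genes changed, 1640 of them lower. With library size alone, 1689 were lower, and the median of all genes moved to 0.063 on the log2 scale. Leaving out each library gave 3652 to 4924 genes. With an estimated correlation 0 lists were called, 0 higher and 0 lower. With fry 4 were, 1 of them higher (nuclear RNA, granule neuron, the Atoh7 region with Atoh7 itself, and heat shock). On the opposite strand the mean CPM of the granule, Purkinje and photoreceptor lists was 43.9, 47.3 and 7.20, and with the unstranded column that of the photoreceptor list was 0.656. The opposite-strand CPM are relative to the reads of that strand alone, 1.62% to 1.88% of the stranded reads. They therefore cannot be set against the main CPM as amounts of RNA.

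The log2 fold changes that changed sign were as follows. With library size alone they were 0.063 for Mcm4, 0.0094 for Hk1, 0.044 for 4930507D05Rik, 0.047 for Stox1 and 0.019 for Tet1. RLE gave 0.0077 for Mcm4, no filter 0.010 for Mcm4 and 0.00013 for Stox1, and the unstranded column 0.020 and 0.00052 for the same genes. Without ribosomal genes Mcm4 was at 0.019, 4930507D05Rik at 0.0080 and Stox1 at 0.0081. With limma-voom Ttr was at -0.036 and Mcm4 at 0.0035, with DESeq2 Mcm4 at 0.012 and Stox1 at 0.0024, and with the replicate block Ttr at -0.018. With the Xist covariate Ttr was at -0.088, Tfap2a at -0.039, Robo3 at 0.016, 2010107G23Rik at -0.00738, Ddx21 at -0.025 and Stox1 at 0.099. With the trend removed Ttr was at -0.023, Hk1 at 0.058, Ddx50 at 0.030 and Tet1 at 0.12. Without WT replicates 2 and 3 Mcm4 was at 0.096, Hkdc1 at 0.26, Srgn at 0.087 and Tet1 at 0.055. Leaving out each library gave -0.18 to 0.37 for Ttr, -0.034 to 0.26 for Tfap2a, -0.038 to 0.038 for Mcm4, -0.026 to 0.085 for 2010107G23Rik, -0.26 to 0.019 for Hkdc1, -0.28 to 0.12 for 4930507D05Rik, -0.18 to 0.050 for Srgn, -0.020 to 0.11 for Ddx21 and -0.072 to 0.095 for Stox1.

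For lists whose direction changed, none called in the main result, the adjusted p with fry was 0.887 for myelin, 0.948 for inner retina and 0.281 for glutamate receptors. With the filter of 50 reads it was 0.975 for myelin, glutamate receptors and small and ribosomal RNA. With library size alone it was 0.941 for glutamate receptors, 0.996 for clock genes and small and ribosomal RNA and 0.903 for sterol synthesis, and with no filter 0.995 for small and ribosomal RNA. With the trend removed it was 0.968 for myelin, 0.715 for axon guidance, 0.755 for clock genes, 0.944 for sterol synthesis and 0.815 for small and ribosomal RNA. Without WT replicates 2 and 3 it was 0.830 for proneural genes, 0.727 for choroid plexus, 0.501 for photoreceptors, 0.895 for inner retina, 0.527 for proliferation and 0.723 for glutamate receptors. Leaving out each library gave 0.399 to 0.976 for myelin, 0.00658 (without enhancer KO replicate 3) to 0.857 for choroid plexus, 0.615 to 0.994 for photoreceptors, 0.479 to 0.988 for inner retina, 0.388 to 0.999 for axon guidance, 0.168 to 0.983 for proliferation, 0.700 to 0.992 for glutamate receptors, 0.732 to 0.976 for clock genes, 0.455 to 0.995 for sterol synthesis, 0.788 to 0.959 for small and ribosomal RNA and 0.0880 to 0.716 for sex-linked genes.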

Other observations

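The tests of less cerebellum and of a background of reads, and the gene families below, were chosen only after the values were seen. Predictions of the other tests were written before their values were seen. Among these, the trend removal was itself added after the data were examined. All 4 Clk genes, kinases of splicing factors, fell (edgeR), with a median log2 fold change of -1.10, and of 11 Srsf splicing factor genes 8 fell and 0 rose, with a median of -0.36. Reads outside exons were fewer in the same enhancer KO libraries, 17.4% against 32.4% in WT. Whether the Clk and Srsf falls are separate from that difference was not tested. Rbm genes were mixed, with 14 of 36 lower and 4 higher and a median of -0.11, or -0.032 with the trend over gene structure removed. Of 94 microRNA genes 65 fell and 0 rose (median -1.50), and of 44 collagen genes 15 fell and 1 rose (median -0.26). Across all 15846 genes tested, 2844 fell and 2120 rose. Of 353 Zfp genes 90 fell and 10 rose, and of 4 Serpina3 genes 2 rose. No median of these families changed sign with RLE, library size alone or the trend over gene structure removed. The microRNA median was -0.75 with the trend removed, and reads on such genes may come from introns of genes around them, since genes in same-strand introns had a median of -1.27 and those on the opposite strand 0.06. Spliced length was the summed length of all annotated exons of a gene, with overlaps counted once. The fifth of genes with the greatest spliced length had 1041 lower and 343 higher, and the fifth with the least 279 lower and 444 higher.

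Several genes split the WT libraries. Tfap2d was at 3.85 CPM in WT replicate 1, 0 and 0.0888 CPM in WT replicates 2 and 3, and 3.98 to 5.95 CPM in enhancer KO, and Six3 at 4.44, 0.0488, 0.118 and 3.80 to 5.06 CPM. Lhx2, Emx2 and Pou4f2 split the same way. Midbrain tissue in WT replicate 1 and the enhancer KO libraries, and less of it in WT replicates 2 and 3, was weighed as a hypothesis. WT replicate 1 was compared with the mean of WT replicates 2 and 3 for 9 midbrain and thalamus genes written down before their levels were looked at. It was above that mean for 8 of them, and over 2-fold for 3, Sox14, Otx1 and Tal1. Gata2 in WT replicate 1 lay below WT replicate 3, and Tal2 below WT replicate 2. Otx1 was at 1.76 CPM in WT replicate 1, 1.03 CPM in WT replicate 2 and 0.385 CPM in WT replicate 3. In enhancer KO, Sox14 (1.17 to 2.02 CPM) and Tal1 (6.45 to 7.66 CPM) lay above WT replicates 2 and 3, while Otx1 (0.468 to 0.839 CPM) lay below WT replicate 2 (1.03 CPM) and Gata2 (3.96 to 4.16 CPM) below WT replicates 1 and 3 (5.49 and 5.56 CPM). The median log2 ratio was 0.22, inside the bound set beforehand for no difference, but the quartiles were 0.12 and 1.21, so the spread reaches beyond that bound. The brainstem and midbrain list averaged 19.4 CPM in WT replicate 1, 15.9 and 14.8 CPM in WT replicates 2 and 3 and 19.6 to 20.5 CPM in enhancer KO. The hypothesis stays open.

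Granule cell markers were lower and Purkinje markers higher in enhancer KO. Less cerebellum beside brainstem in the enhancer KO dissections would lower both, and 12 Purkinje genes rose while 0 fell, which is part of the pattern and leaves it open for the granule markers alone. A trend over intron length, spliced length and GC content is argued against as the whole cause by the median of the granule list, -0.53 with the trend removed against -0.64 before. A different ratio of cell types or of their transcripts, through genotype, dissection or a batch, stays open. With only WT replicate 1 left on the WT side, the granule median was -0.41.

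Atoh7 was lower in enhancer KO, which the removal of its enhancer may explain as a hypothesis. A trend over gene structure is argued against by its log2 fold change of -1.46 ± 0.206 (SE) with the trend removed. Relative to the mean of the granule list, its change was -0.75 ± 0.312 (SE). Members of that list ranged from -1.17 to -0.40, a spread that this test does not allow for. Less RNA from granule cells therefore stays open. A background of reads on weakly expressed genes that is larger in WT stays open: 37 of 973 genes of similar level had a log2 fold change as low or lower, which puts Atoh7 at percentile 3.80.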
